A study of Bos taurus with 6 samples.

How the data were processed

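The samples were polyadenylated RNA libraries from the peripheral blood of dairy cows (Bos taurus), 3 from cows 30 days after breeding and 3 from non-pregnant cows. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and complementary DNA was made by random priming, ligated to adapters, amplified and sequenced on an Illumina instrument. The labels state neither strand marking nor molecular identifiers. Per the labels, the groups hold 15 and 10 cows and 3 biological replicates each, and they do not say whether a library is 1 cow or a pool.

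Per the submitters' processing notes, FastQC 0.12.1, Trimmomatic 0.38, HISAT2 2.2.1, StringTie 2.1.7 and DESeq2 1.34.0 were used with the bosTau9 genome build. The notes as used here give these tools no role or order, and the annotation and counting settings are not given in the sources used here. The authors deposited a table of estimated counts per gene, written as whole numbers and not scaled. Of 391 low-count genes compared with the deposited TPM, 48 (12.3%) had library ratios within 2% of those that whole reads would give, so the count table was taken to hold estimates rounded to whole numbers. The authors also deposited a table of TPM values for the same genes, in which each library sums to 1000000. Both tables list 28786 genes, of which 8214 had no count in any library. Gene names are those in the tables, and 24366 (84.6%) matched a symbol in the RefSeq gene table of the ARS-UCD2.0 assembly, which was used for names and gene order alone. No coordinates are printed, since that assembly is not the one named in the notes.

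How the counts were made can affect the values. Without strand marking, reads of overlapping or antisense genes cannot be told apart. Reads shared by near-identical genes (the alpha globins HBA and HBA1, the WC1 family, the MHC genes) may be divided by the estimator, so their split is uncertain, and polymorphic MHC genes also depend on how the cows' alleles match the reference. Capture on oligo(dT) removes most ribosomal RNA, and the ribosomal RNA gene RN18S1 took 0.956% to 3.74% of counts. Mitochondrially encoded genes took 9.64% to 10.7% of counts, and the 10 most abundant genes of a library 12.0% to 15.4%.

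The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was the quasi-likelihood F-test of edgeR on the deposited estimated counts, as whole numbers, with TMM scaling, the filterByExpr filter (15139 genes kept) and Benjamini-Hochberg adjustment at 0.05, pregnant against non-pregnant, with no covariate. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change was derived from the F statistic, and intervals are at 95%. The common biological coefficient of variation was 0.158, and the median log2 fold change of all tested genes was -0.01. Between libraries of 1 group the chi-square per gene was at least 24.3, so no library was counted as a copy of another.

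Before the data were examined, 26 gene lists were fixed: interferon-stimulated, mature neutrophil, immature neutrophil granule, monocyte, T cell, gamma delta T cell, B cell, natural killer and cytotoxic, platelet, red cell, eosinophil and basophil, dendritic, MHC class II, MHC class I, NF-kB inflammatory, pattern recognition, immune tolerance, trophoblast, steroid hormone response, prostaglandin, DNA methylation, cell cycle, ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation, and immediate early genes. Of these, 25 had at least 3 tested members. Lists were tested with camera in limma on log2 CPM (prior count 2) at its preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Members of a list were also adjusted over the list alone, with no adjustment across lists, so a gene's call depends on its list. For 11 cell type lists the mean log2 CPM per library was compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

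The rule for named genes was also fixed before the data were examined. It took up to 10 genes per direction with the largest change among those past the threshold, with a symbol, a mean CPM of at least 5 and no overlap of the group ranges. Where fewer than 5 met it, the direction was filled to 5 with the genes of smallest p that have a symbol and that mean CPM, given as values. From each list it took up to 3 members past the threshold or, with none past it, the 1 of smallest p. It always took ISG15, MX1, MX2, OAS1Y, RSAD2, DNMT1, DNMT3A and TET2. This gave 39 genes, of which 38 are plotted, and some genes that the rule or a list takes are not reported here. All other genes named in the text were chosen after their values were seen.

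The gene tests of edgeR (without and with the block), DESeq2 and limma on log2 TPM, and the list tests camera and fry, were run on simulated counts of 14843 genes with the means and library sizes of these libraries, in which 50 genes each were changed 1.3, 1.5, 2 and 3-fold. For this comparison edgeR recovered 16%, 46%, 58% and 86% of them, DESeq2 24%, 54%, 70% and 90%, and limma on log2 TPM (11948 genes) 8%, 24%, 50% and 84%. A simulated list shifted by 0.3 on the log2 scale was called by camera at the preset correlation and by fry, and not with an estimated correlation (adjusted p = 0.083), and 0 of 24 other lists were called. Each simulated gene was drawn independently, while the estimated correlation within the real lists reached 0.73 (ribosomal protein). The simulation therefore does not show how often camera at its preset correlation calls such lists in error. Other splits of the 6 real libraries into 3 and 3 gave 3 to 14 lists past camera. Limma-voom, robust edgeR and the exact permutation test were not run on simulated counts.

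The alternatives tried were the DESeq2 size factors, the DESeq2 Wald test, no filter and a stricter filter on low counts, the replicate number as a block, each library left out in turn, globin, mitochondrial and the 10 most abundant genes left out before scaling, a 2-fold minimum, and limma with trend on log2(TPM + 1) for genes with a mean TPM of at least 1, on log2(TPM + 0.1), and without that filter. Limma-voom and robust edgeR were added after the data were seen. GC content was not analysed here.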

Results

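Polyadenylated RNA from peripheral blood of dairy cows was sequenced in 6 libraries. Of these, 3 came from cows sampled 30 days after breeding, drawn from a study group of 15 animals, and 3 from non-pregnant cows, drawn from a group of 10. The labels do not say whether a library holds 1 cow or a pool, nor whether whole blood or a leukocyte fraction was used, so the p-values measure the spread between these libraries. Total counts per library were 45158526, 41177544 and 45126254 for non-pregnant libraries 1, 2 and 3, and 44132692, 45406892 and 46450586 for pregnant libraries 1, 2 and 3. Genes with at least 1 count numbered 17038 to 17639 per library, and 15139 genes had enough counts to be tested. Non-pregnant library 2 had the fewest counts and the highest shares of the ribosomal RNA gene RN18S1 (3.74%, others 0.956% to 2.01%) and of the 10 most abundant genes (15.4%). Gene levels are given as mean ± SD in TMM-normalised CPM (counts per 1000000 counts) over 3 libraries per group, and changes as pregnant minus non-pregnant log2 fold change ± standard error.

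The comparison asks which blood transcripts differ between cows in early pregnancy and non-pregnant cows. No day after breeding is given for the non-pregnant cows, so time since breeding cannot be told apart from pregnancy. By camera at its preset correlation, marker genes of mature neutrophils, of eosinophils and basophils, of platelets and of red cells lay higher as groups in the pregnant libraries, with median folds of 1.20, 1.40, 1.25 and 1.56. MHC class II genes, which present antigen, lay higher by a median fold of 1.16, while genes of dividing cells and T cell genes lay lower, with median log2 fold changes of -0.22 and -0.14. None of these calls held with an estimated correlation (adjusted p = 0.319 for platelets and adjusted p = 0.314 for each of the others) or with fry. Inflammatory genes driven by NF-kB (median fold 1.40; adjusted p = 0.314 with an estimated correlation) and ribosomal protein genes (median log2 fold change -0.09; adjusted p = 0.670 with an estimated correlation) also passed at the preset correlation, but these calls were lost without pregnant library 1 (median 0.09) and without non-pregnant library 2 (-0.03). The interferon-stimulated genes, which respond in cattle blood to interferon tau from the conceptus, had a median log2 fold change of 0.0037 over 47 genes. They did not pass the same test. All pregnant libraries were from 30 days after breeding, so a response on earlier days was not examined.

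No single gene passed the test over all genes. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 0 of 15139 genes, with a smallest adjusted p of 0.118. At an unadjusted p under 0.05 there were 1530 genes, 896 higher and 634 lower, where chance gives 757. DESeq2 called 284 genes, 223 higher and 61 lower, while limma on the TPM values called 0, as did limma-voom and robust edgeR on the counts, both added after the data were seen. By its own filters DESeq2 gave 6751 of the 15139 genes no adjusted p, LTF, NELL2, PTGS2, WC1-12 and ATF3 among them. Its calls over all genes therefore cover the remaining genes alone. The group ranges did not overlap for 2386 genes (15.8%), against 10% by chance for 3 against 3. On simulated counts for these libraries, edgeR recovered 46% of genes changed 1.5-fold and 86% of genes changed 3-fold, with 7 false among 112 calls, and DESeq2 made 21 false among 144 calls. The values that follow are therefore those of genes short of the all-gene threshold, and a gene is said to rise or fall only where it passed the edgeR test when adjusted over the list alone. There were 53 such calls, with no adjustment across lists. Of these, 15 held without any 1 of the 6 libraries, and in 0 of the 53 did leaving out a library turn the sign. A call can also be lost because fewer libraries remain, with little change in its estimate.

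The genes of smallest p and a higher level in pregnancy were IL1RN, NCF1, NELL2, IL1R1 and HBA. IL1RN, which encodes the interleukin-1 receptor antagonist, went from 314.7 ± 14.3 to 437 ± 22.1 CPM (log2 fold change 0.47 ± 0.07, edgeR adjusted p = 0.118). NCF1, a subunit of the phagocyte NADPH oxidase, went from 261 ± 14.1 to 385 ± 46.6 CPM (0.56 ± 0.09). IL1R1, the signalling receptor of interleukin-1, stood at 51.3 ± 5.73 and 74.9 ± 4.27 CPM (0.55 ± 0.09). NELL2, a secreted glycoprotein, was a low gene that stood at 4.57 ± 0.30 and 8.92 ± 1.01 CPM (0.96 ± 0.16). Some lower genes without a symbol or below a mean CPM of 5 had a smaller p than those named here. Among the others, those lower with the smallest p were TPR, a nuclear pore protein (-0.53 ± 0.11), USP25, a deubiquitinase (-0.38 ± 0.08), SCML4 (-0.39 ± 0.09), TET1, which oxidises 5-methylcytosine (-0.60 ± 0.14), and IFI47, an interferon-inducible GTPase (-0.49 ± 0.11), each with an edgeR adjusted p of 0.152. Group ranges did not overlap for any of these 10 genes. USP25 had the opposite sign in the TPM values (0.08 ± 0.11), so its direction is open. DESeq2 placed 19 of the 39 named genes past its threshold, IL1RN, NCF1, IL1R1, HBA and the 5 lower genes among them.

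**Figure D1:**
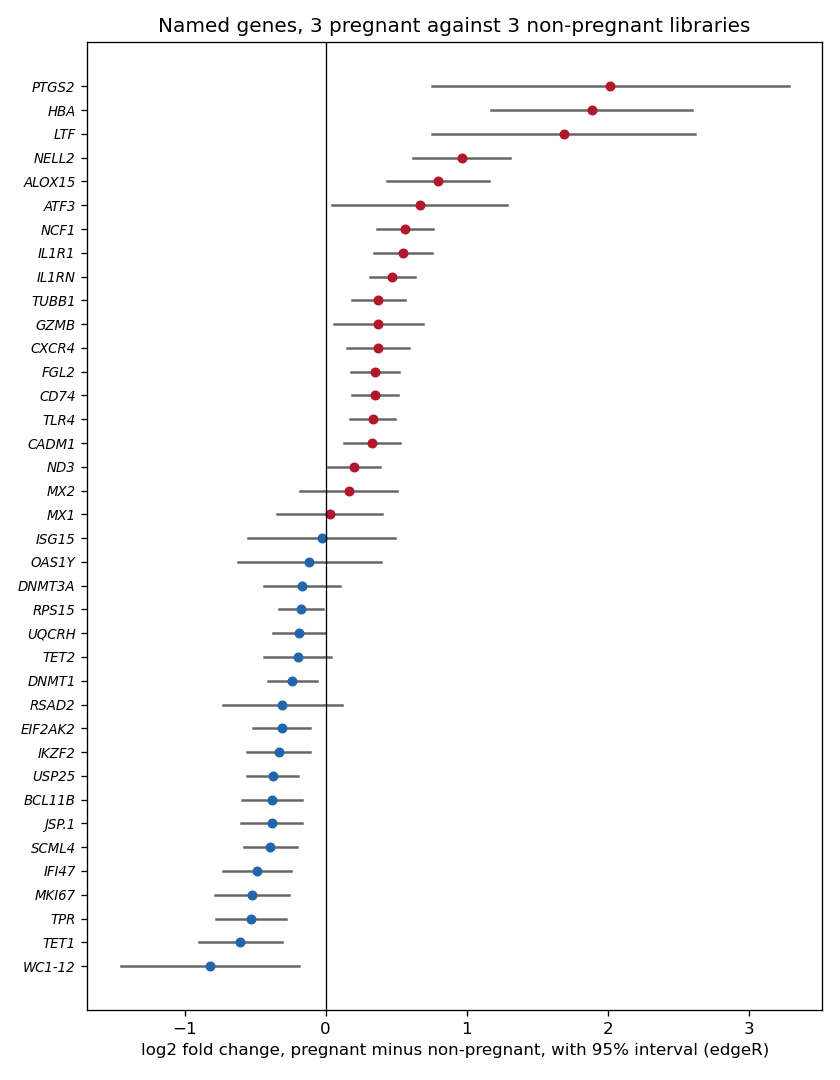
Log2 fold change of 38 of the 39 named genes, pregnant minus non-pregnant (x axis), with points for the edgeR estimate and lines for its 95% interval, 3 libraries per group. PTGS2 lies highest at 2.02 and WC1-12 lowest at -0.82, and the intervals of ISG15, MX1, MX2, OAS1Y and RSAD2 include 0.

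Of 19 tested mature neutrophil genes, 18 were higher in the pregnant libraries (camera adjusted p = 5.74e-07; adjusted p = 0.314 with an estimated correlation). By edgeR 0 passed over all genes, where DESeq2 called 6, all higher, 11 had an unadjusted p under 0.05, and adjusted over the list alone 10 rose and 0 fell. NCF1 rose most clearly (edgeR p adjusted over the list alone 9.0e-04). The interleukin-8 receptors CXCR1 and CXCR2 rose by 0.47 ± 0.11 and 0.48 ± 0.11, CXCR2 from 347 ± 45.0 to 484 ± 54.6 CPM. PADI4, which citrullinates histones in neutrophils, rose by 0.38 ± 0.10, and the alarmin S100A9 by 0.26 ± 0.09. MMP25, MMP9, MGAM and TGM3 also rose. Without pregnant library 2 the changes of S100A9 and TGM3 were 0.15 and 0.19, against 0.26 and 0.44 with it, and the calls that held without any 1 library were 4, NCF1, CXCR1, CXCR2 and PADI4. Of 9 granule genes typical of immature neutrophils, 8 were higher, with a median of 0.47 (camera adjusted p = 9.22e-04; adjusted p = 0.314 with an estimated correlation). Over all genes edgeR and DESeq2 called 0 of them, 5 had an unadjusted p under 0.05, and adjusted over the list alone 2 rose. These were the low genes LTF, which encodes lactoferrin (1.14 ± 0.82 to 3.70 ± 0.98 CPM), and MPO, myeloperoxidase (2.71 ± 0.72 to 5.76 ± 2.72 CPM). LTF read 2.07 CPM in non-pregnant library 1, without which its log2 fold change was 2.43 against 1.69 with it. Over all alternatives tried its lowest value was 0.94. Both calls were lost without non-pregnant library 3 (LTF 1.51, MPO 0.89) or pregnant library 3 (LTF 1.55, MPO 0.63).

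Eosinophil and basophil markers were higher for all 12 tested genes, with a median of 0.49 (camera adjusted p = 1.13e-04; adjusted p = 0.314 with an estimated correlation). By edgeR over all genes 0 passed (DESeq2 1, CSF2RB; 6 at an unadjusted p under 0.05), and 3 rose when adjusted over the list alone: ALOX15, a lipoxygenase of eosinophils (60.01 ± 15.3 to 104.1 ± 21.0 CPM), CSF2RB, the shared receptor chain of interleukin-3, interleukin-5 and GM-CSF (0.27 ± 0.08), and IL5RA, the interleukin-5 receptor (0.67 ± 0.22). Of these, ALOX15 alone kept its call without any 1 library. Without pregnant library 3 the median was 0.24 and the list still passed. In the platelet list of 17 genes, 14 were higher, with a median of 0.32 (camera adjusted p = 3.56e-04; adjusted p = 0.319 with an estimated correlation). Platelet genes past the threshold adjusted over the list alone were 6, of which 5 rose and 1 fell, and over all genes edgeR called 0 and DESeq2 4, all higher, with 8 at an unadjusted p under 0.05. TUBB1, the platelet tubulin, rose from 1699 ± 183 to 2202 ± 124 CPM, followed by RGS18, F13A1, ITGA2B and SELP, whose change was 0.26 without non-pregnant library 1 against 0.40 with it, the call being lost. CLEC1B, a platelet lectin receptor near the low end of the tested range, fell from 1.36 ± 0.22 to 0.486 ± 0.251 CPM. The calls of TUBB1, RGS18, F13A1 and ITGA2B held without any 1 library, and those of SELP and CLEC1B did not.

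Red cell genes showed the largest median of the 25 tested lists, 0.64 over 22 genes, 19 of them higher (camera adjusted p = 5.55e-05; adjusted p = 0.314 with an estimated correlation). There were 8 genes that rose and 1 that fell adjusted over the list alone, against 0 over all genes by edgeR and 3, all higher, by DESeq2, and 12 had an unadjusted p under 0.05. HBB, the beta globin gene, rose from 2316 ± 669 to 4981 ± 2821 CPM, and SLC4A1, the band 3 anion exchanger, from 0.756 ± 0.208 to 3.21 ± 1.3 CPM. ALAS2, the first enzyme of haem synthesis in red cell precursors, rose from 99.6 ± 23.5 to 213 ± 118 CPM, and GATA1, an erythroid and megakaryocyte transcription factor, from 13.1 ± 2.4 to 18.7 ± 1.1 CPM. HBA and HBA1, near-identical alpha globin genes whose reads cannot be divided with certainty, rose by 1.89 ± 0.33 and 1.73 ± 0.30. CA2 and BLVRB also rose. Globin transcripts took 0.375%, 0.207% and 0.293% of counts in non-pregnant libraries 1, 2 and 3, and 0.676%, 0.310% and 1.06% in pregnant libraries 1, 2 and 3. Without pregnant library 3, which had the most globin, the median of the red cell list was 0.40 and the list still passed, but the calls of HBB, ALAS2 and CA2 were lost, their log2 fold changes being 0.60, 0.62 and 0.56. Of the 9 calls, 3 held without any 1 library, HBA, HBA1 and SLC4A1.

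T cell genes were lower for 19 of 24 members, with a median of -0.14 (camera adjusted p = 0.00106; adjusted p = 0.314 with an estimated correlation). By edgeR 0 passed singly, adjusted over the list alone or over all genes, with 5 at an unadjusted p under 0.05, and DESeq2 called 2 over all genes, CD247 and BCL11B. BCL11B, a T lineage transcription factor, stood at 138 ± 18.7 and 106 ± 7.0 CPM, and CD247, the zeta chain of the T cell receptor complex, at 360 ± 36.9 and 283 ± 35.9 CPM. Gamma delta T cell genes had the lowest median of all lists, -0.48 over 9 genes, 8 of them lower (camera adjusted p = 0.0202; adjusted p = 0.549 with an estimated correlation), with 0 past adjusted over the list alone and 0 over all genes by edgeR and DESeq2, 3 at an unadjusted p under 0.05. WC1-12, of the scavenger receptor family that marks these cells and whose members share sequence, stood at 11.97 ± 4.66 and 6.78 ± 2.36 CPM (log2 difference -0.82, and -0.51 without non-pregnant library 1). The gamma delta call was lost without non-pregnant library 1 (median -0.26) or pregnant library 2 (-0.25), and without pregnant library 1 the median was -0.77. B cell genes did not pass (median 0.06, 20 genes, camera adjusted p = 0.0874), with 1 gene past adjusted over the list alone, 0 over all genes by edgeR, 1 by DESeq2, and 4 at an unadjusted p under 0.05. Natural killer and cytotoxic genes did not pass either (median 0.04, 21 genes, camera adjusted p = 0.552), with 0 past adjusted over the list alone by edgeR, 0 over all genes by edgeR and DESeq2, and 1, GZMB, at an unadjusted p under 0.05 (0.37 ± 0.14, and 0.20 without pregnant library 3). Without non-pregnant library 2 the natural killer list passed with a median of 0.15, and the B cell list passed without non-pregnant library 2, non-pregnant library 3 or pregnant library 1 (medians 0.0917, 0.0871 and 0.0926). The B cell median was 0.0212 without non-pregnant library 1, 0.0409 without pregnant library 2 and 0.0576 without pregnant library 3.

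**Figure D2:**
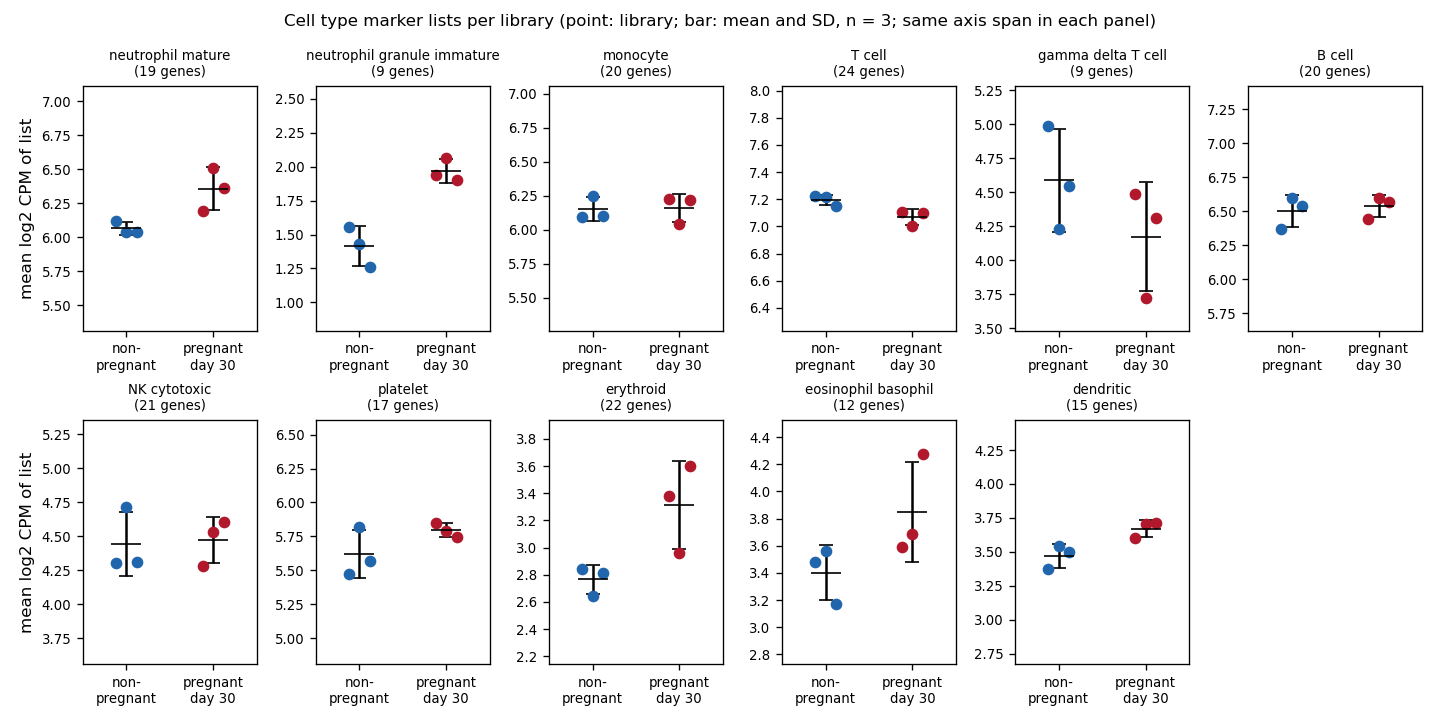
Mean log2 CPM of each of the 11 cell type marker lists (y axis) in each library, with points for libraries and bars for mean and SD over 3 libraries. The groups did not overlap in 6 lists, neutrophil, granule, eosinophil and basophil, red cell, dendritic (higher in pregnancy) and T cell (lower).

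The mean level of a list in each library gave the same picture for 6 of the 11 cell type lists, whose groups did not overlap. Mature neutrophil genes averaged 6.07 ± 0.05 and 6.36 ± 0.16 log2 CPM, immature granule genes 1.42 ± 0.15 and 1.97 ± 0.09, and T cell genes 7.20 ± 0.04 and 7.07 ± 0.06. Red cell genes differed by 0.55, eosinophil and basophil genes by 0.45 and dendritic genes by 0.20. The exact two-sided permutation test gave p = 0.1 for each of the 6, the smallest that 3 against 3 allows, and 0.183 after adjustment over the 11 lists. Platelet genes differed by 0.18 in the mean, but the groups overlapped (exact permutation p = 0.3). They averaged 5.82 log2 CPM in non-pregnant library 2 against 5.75 to 5.85 in the pregnant libraries. Gamma delta T cell genes differed by -0.41 and overlapped too (exact permutation p = 0.4). Monocyte genes differed by 0.01 in the mean (exact permutation p = 1), although their median of 0.14 over 20 genes passed camera (adjusted p = 0.0323; adjusted p = 0.538 with an estimated correlation). Monocyte genes that rose adjusted over the list alone were FGL2 (0.35 ± 0.08) and PLBD1 (0.27 ± 0.08), 2 in all against 0 over all genes by edgeR, while DESeq2 called these same 2 and 7 had an unadjusted p under 0.05. Both calls were lost without non-pregnant library 3 (0.30 and 0.29) or pregnant library 2 (0.31 and 0.27), and that of PLBD1 without non-pregnant library 1 (0.22) or pregnant library 3 (0.25). The monocyte list call was lost without any 1 of non-pregnant libraries 1 and 3 and pregnant libraries 1 and 3 (medians 0.0861, 0.118, 0.0835 and 0.165). Dendritic cell genes had a median of 0.13 over 15 genes (camera adjusted p = 0.0470; adjusted p = 0.314 with an estimated correlation), with 0 past adjusted over the list alone or over all genes by edgeR, 1 by DESeq2, 4 at an unadjusted p under 0.05, and CADM1 at 0.33 ± 0.09. That call was lost without non-pregnant library 1 or 3 or pregnant library 2 or 3 (medians 0.102, 0.0712, 0.0811 and 0.136).

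MHC class II genes were higher for 12 of 13 members, with a median of 0.22 (camera adjusted p = 5.24e-05; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone 6 rose, and over all genes edgeR called 0 and DESeq2 2, CD74 and BOLA-DRA, with 7 at an unadjusted p under 0.05. CD74, the invariant chain, rose from 7620 ± 597 to 9709 ± 392 CPM, BOLA-DRA from 2441 ± 201 to 2969 ± 114 CPM, and CIITA, the class II transactivator, from 173 ± 4.45 to 201 ± 9.79 CPM. DSB, BOLA-DRB3 and BOLA-DOB also rose, and of the 6 calls those of CD74 and DSB held without any 1 library. MHC class I genes did not pass (median -0.05, 17 genes, camera adjusted p = 0.390), and JSP.1, a polymorphic class I heavy chain gene, fell by 0.38 on the log2 scale (SE 0.10) as 1 gene adjusted over the list alone, the only 1 at an unadjusted p under 0.05, with 0 over all genes by edgeR and 1 by DESeq2. The call of JSP.1 was lost without non-pregnant library 2 or 3 or pregnant library 2 or 3 (-0.30, -0.36, -0.32 and -0.38). Without non-pregnant library 1 the class I list passed with a median of -0.10. Its median was -0.01 without non-pregnant library 2, -0.02 without non-pregnant library 3 and -0.03 without pregnant library 1.

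Inflammatory genes driven by NF-kB were higher for 23 of 24 members, with a median of 0.48 (camera adjusted p = 1.17e-04; adjusted p = 0.314 with an estimated correlation). In this list 3 genes rose adjusted over the list alone, and over all genes edgeR called 0 and DESeq2 1, IL1RN, with 9 at an unadjusted p under 0.05. IL1RN was followed by IL1B, the cytokine it opposes (102 ± 25.1 to 153 ± 31.6 CPM), and PTGS2, the inducible prostaglandin synthase, which read 9.93 CPM in pregnant library 1 and 2.12 and 1.57 CPM in the other pregnant libraries. Without pregnant library 1 the median was 0.09 and the call was lost, as were those of PTGS2 (0.72 against 2.02 with it) and IL1B (0.40). The PTGS2 call was also lost without non-pregnant library 1, 2 or 3 (1.81, 2.14 and 2.13). The IL1B call was also lost without non-pregnant library 2 or 3 (0.41 and 0.58), while that of IL1RN held without any 1 library. Losses where the estimate did not shrink, as for PTGS2 at 2.14 and 2.13, can come from fewer libraries alone. Pattern recognition genes had a median of 0.11, with 18 of 21 members higher (camera adjusted p = 1.88e-04; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone 3 rose, the endotoxin receptor TLR4 (63.5 ± 1.5 to 80.1 ± 3.05 CPM), its adaptor MYD88 (0.31 ± 0.07) and the beta-glucan receptor CLEC7A (1.04 ± 0.26), while over all genes edgeR called 0 and DESeq2 2, TLR4 and MYD88, with 4 at an unadjusted p under 0.05. Without non-pregnant library 2 their median was 0.20, and without non-pregnant library 3 the calls of TLR4, MYD88 and CLEC7A were lost (0.32, 0.33 and 0.85), that of CLEC7A also without pregnant library 3 (0.92). The mature neutrophil list averaged 6.19 log2 CPM in pregnant library 1, 6.51 in pregnant library 2 and 6.37 in pregnant library 3, lowest in the library on which the inflammatory call rested. ATF3, an immediate early gene, also read high there (14.9 CPM, and 6.24 and 6.95 CPM in the other pregnant libraries). The immediate early list as a whole did not pass (median 0.04, and -0.08 without pregnant library 1). Whether sample handling raised the inflammatory genes was not tested.

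Cell cycle genes were lower for 23 of 25 members, with a median of -0.22 (camera adjusted p = 5.74e-07; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone 5 fell, and over all genes edgeR called 0 and DESeq2 4, all lower (MKI67, MCM6, TOP2A and RRM2), with 7 at an unadjusted p under 0.05. The proliferation marker MKI67 fell from 66.8 ± 10.5 to 46.5 ± 6.03 CPM, the replicative helicase subunit MCM6 from 58.9 ± 1.48 to 46.7 ± 2.71 CPM, and TOP2A, RRM2 and PLK1 fell by 0.58, 0.44 and 0.38 on the log2 scale. All 5 calls were lost without pregnant library 1 or pregnant library 2, those of MKI67, MCM6, RRM2 and PLK1 without non-pregnant library 3, those of TOP2A and RRM2 without non-pregnant library 2, and that of PLK1 without pregnant library 3. Their log2 fold changes then ran from -0.60 (TOP2A without pregnant library 1) to -0.29 (RRM2 without non-pregnant library 2). Ribosomal protein genes were lower for 72 of 78 members, with a median of -0.09 (camera adjusted p = 5.55e-05; adjusted p = 0.670 with an estimated correlation). Of these 0 passed adjusted over the list alone by edgeR or over all genes by edgeR and DESeq2, 2 had an unadjusted p under 0.05, and RPS15 stood at 1449 ± 45.0 and 1286 ± 83.8 CPM. The ribosomal call was lost without non-pregnant library 2 (median -0.03), and the median was -0.06 without pregnant library 1 and -0.14 without pregnant library 2. Non-pregnant library 2 had the highest share of ribosomal protein counts, 10.2% against 8.85% to 9.83% in the others, beside its high RN18S1. The T cell list averaged 7.15 to 7.22 log2 CPM in the non-pregnant and 7.0 to 7.11 in the pregnant libraries.

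**Figure D3:**
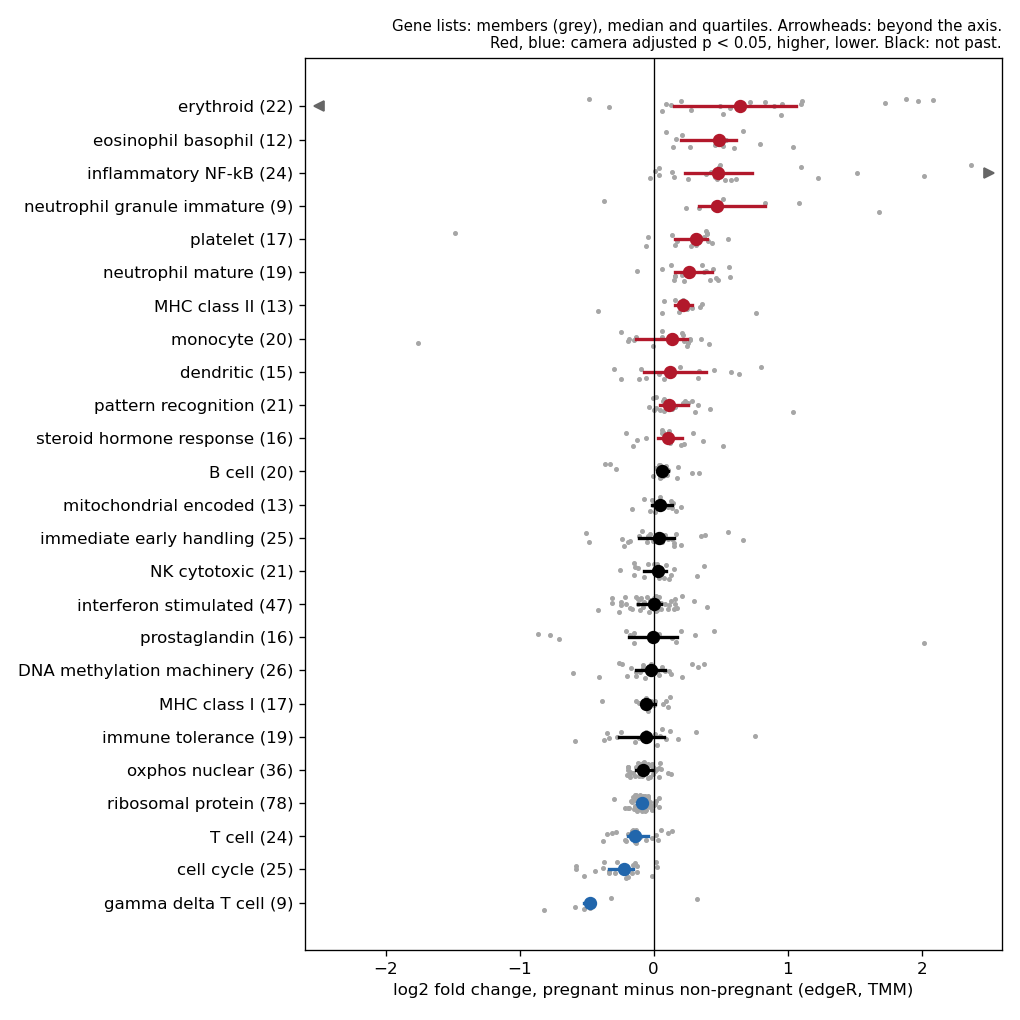
Log2 fold change, pregnant minus non-pregnant (x axis), of the members of the 25 tested gene lists (grey points, with the number tested in brackets and arrowheads for members beyond the axis), with each list's median (large point) and quartiles (bar). Red and blue mark the 15 lists past camera, 11 higher and 4 lower, and the red cell list has the highest median at 0.64.

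Interferon-stimulated genes went both ways, 24 higher and 23 lower, with a mean of -0.02 against a median of 0.0037 (camera, direction lower, adjusted p = 0.648). By edgeR 0 passed adjusted over the list alone and 0 over all genes, as by DESeq2, with 5 at an unadjusted p under 0.05. ISG15, a ubiquitin-like protein used as an early pregnancy marker in cattle blood, stood at 53.2 ± 16.6 and 52.2 ± 19.1 CPM, a log2 difference of -0.03 with a 95% interval from -0.55 to 0.49. The antiviral GTPases MX1 and MX2 differed by 0.03 (interval -0.35 to 0.40) and 0.16 (-0.18 to 0.51), OAS1Y by -0.12 (-0.62 to 0.39) and RSAD2 by -0.31 (-0.73 to 0.11). EIF2AK2, the double-stranded RNA kinase, had the smallest p of the list (-0.31 ± 0.09). These values are for 30 days after breeding alone, and no earlier day was sampled in these libraries. Without pregnant library 2 the list passed in the lower direction with a median of -0.07, and the signs of ISG15, MX1, MX2 and OAS1Y turned with the library left out. RSAD2 differed by -0.10 without non-pregnant library 3, -0.11 without pregnant library 1 and -0.49 without pregnant library 2.

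Genes that write, read or erase DNA methylation did not pass as a list (median -0.02, 26 genes, camera adjusted p = 0.38). By edgeR 1 rose and 1 fell adjusted over the list alone, and 0 passed over all genes, where DESeq2 called the same 2 and 6 had an unadjusted p under 0.05. TET1 fell from 11.8 ± 0.37 to 7.75 ± 0.84 CPM, and AHCY, which clears the product of methyl transfer, rose from 351 ± 37.4 to 441 ± 28.1 CPM. Both calls were lost without non-pregnant library 3 (TET1 -0.62, AHCY 0.30), pregnant library 2 (-0.52 and 0.29) or pregnant library 3 (-0.64 and 0.31), and that of AHCY without non-pregnant library 1 (0.28). Over all alternatives tried the change of TET1 ran from -0.66 to -0.35. The maintenance methyltransferase DNMT1 stood at 59.1 ± 2.25 and 50.1 ± 2.69 CPM (-0.24, interval -0.41 to -0.06, edgeR adjusted p = 0.301), the de novo methyltransferase DNMT3A differed by -0.17 (-0.44 to 0.10) and TET2 by -0.20 (-0.43 to 0.04). Without non-pregnant library 1 DNMT3A differed by -0.07 and TET2 by -0.11, without pregnant library 3 TET2 by -0.10, and DNMT3A by -0.30 without non-pregnant library 2 and -0.26 without pregnant library 1. DNMT1 ranges did not overlap, and those of DNMT3A and TET2 did.

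Placental transcripts were looked for by name. Of 26 trophoblast names in the table, 25 had 0 counts in all 3 pregnant libraries and, together, 6 counts in the non-pregnant ones. In the pregnant libraries 3 counts correspond to 0.0646 to 0.0680 CPM of the total counts, without TMM scaling. These are floors for counting error alone, and such transcripts were not detectable at this depth. The name PAG1 was tested, but it lies between ZNF704 and FABP5 in the RefSeq gene order, apart from the pregnancy-associated glycoproteins, and its counts were 14436 to 16779 in pregnant and 15359 to 17950 in non-pregnant libraries.

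The steroid hormone response list was fixed with hormone receptors beside response genes, so it is not a pure measure of response. It had a median of 0.11 over 16 genes (camera adjusted p = 0.0470, and adjusted p = 0.497 with an estimated correlation). By edgeR 0 passed adjusted over the list alone or over all genes, DESeq2 called 1, CXCR4, and 5 had an unadjusted p under 0.05. CXCR4 stood at 70.1 ± 9.44 and 90.5 ± 7.23 CPM. The call of the list was lost without non-pregnant library 2 or 3 or pregnant library 1 (medians 0.0841, 0.0565 and 0.0293). Immune tolerance genes (median -0.05, 19 genes, camera adjusted p = 0.38) and prostaglandin genes (median -0.0042 but a higher test direction, 16 genes, camera adjusted p = 0.856) did not pass. IKZF2, of regulatory T cells, stood at 44.8 ± 4.39 and 35.6 ± 3.48 CPM. Mitochondrially encoded genes (median 0.05, 13 genes, camera adjusted p = 0.139, ND3 0.20 ± 0.08, and 0.13 without pregnant library 3), nuclear genes of oxidative phosphorylation (median -0.08, 36 genes, camera adjusted p = 0.0874, UQCRH -0.19 ± 0.08) and immediate early genes, which respond to sample handling (median 0.04, 25 genes, camera adjusted p = 0.389, ATF3 0.67 ± 0.29), did not pass. ATF3 read 14.9 CPM in pregnant library 1 and 6.24 and 6.95 CPM in the other pregnant libraries, and without the former its change was 0.16. In these 5 lists 0 genes passed adjusted over the list alone by edgeR or over all genes by edgeR and DESeq2, and 4, 3, 3, 1 and 2 had an unadjusted p under 0.05. PTGS2 belongs to both the prostaglandin and the NF-kB lists, and it passed adjusted over the latter alone but not over the former. Leaving out non-pregnant library 1 brought the mitochondrial, oxidative phosphorylation and immediate early lists past the threshold (medians 0.15, -0.08 and 0.17). Leaving out pregnant library 2 did so for the mitochondrial and oxidative phosphorylation lists (0.12 and -0.09), and non-pregnant library 3 for the latter (-0.12).

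In all, 15 of 25 lists passed camera at its preset correlation of 0.01, and 0 passed with an estimated correlation (smallest adjusted p 0.314) or with fry (smallest adjusted p 0.0617). Of the 15 lists, 9 passed without any 1 of the 6 libraries: mature neutrophil, granule, eosinophil and basophil, platelet, red cell, T cell, MHC class II, pattern recognition and cell cycle.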

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

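The split test in this part was set before its result was seen, and the genes named were chosen after their counts were seen. Outside the comparisons of the report, among the 13647 genes with too few counts to be tested, 23 had at least 3 counts in each pregnant library and 0 counts in each non-pregnant library, and 28 showed the opposite. TFAP2C, a transcription factor of trophoblast and epithelium, had 7, 3 and 7 counts in pregnant libraries 1, 2 and 3 and 0 in the others. The 25 trophoblast names other than PAG1 had 0 counts in the pregnant libraries, so TFAP2C is not read as placental RNA. The cilium gene DRC1 had 6, 15 and 5 counts in pregnant libraries 1, 2 and 3. Of genes seen in non-pregnant blood alone, IL36A had 8, 9 and 13 counts. Groups made by the other splits of the same libraries held 15 to 43 such genes over 18 groups. With tested genes included, 58 genes were detected in 1 group alone, 5 of the 10 splits of the 6 libraries gave as many, and the highest other split gave 71. The 10 splits are too few for a share under 0.05, and no biological explanation was tested for these genes.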

How the results depend on the processing

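Limma-voom and robust edgeR were chosen after seeing the data, and both called 0 genes. The edgeR count of 0 genes (1530 at an unadjusted p under 0.05) moved to 284 with DESeq2 (223 higher, 61 lower) and to 31 with no filter on low counts (26 higher, 5 lower). All 284 DESeq2 calls had the same sign in edgeR with an unadjusted p under 0.05, a median edgeR adjusted p of 0.176, and 269 had ranges apart. The count was 48 with the replicate number as a block (31 higher, 17 lower, and 30 shared with DESeq2). Same-numbered libraries deviated together with correlations of 0.07, 0.01 and -0.04 across genes, and not every library matched its own number best. No pairing was seen, but so few correlations cannot exclude one. Leaving out 1 library gave 0 to 13 genes, 0 to 6 higher and 0 to 7 lower; the 13 came without non-pregnant library 2, 5 without pregnant library 2 and 1 without non-pregnant library 1. Limma on TPM in 3 versions, the stricter filter, the DESeq2 size factors, abundant genes left out and a 2-fold minimum gave 0, and the scaling alternatives shifted the median of all genes by at most 0.000659. The count of 15 lists became 0 with an estimated correlation, 0 with fry, 17 with DESeq2 statistics (B cell and oxidative phosphorylation added), 13 with the block (monocyte and dendritic lost), and 13 to 16 with 1 library left out. The 6 cell type lists with groups apart became 5 to 7. USP25 reversed in limma on TPM (0.078), with a pseudocount of 0.1 (0.083) and without the filter (0.078), and the cause was not tested. With 1 library left out, signs turned for MX1 (-0.15 to 0.28), ISG15 (-0.34 to 0.25), OAS1Y (-0.41 to 0.17) and MX2 (-0.074 to 0.33), and for the medians of the interferon (-0.074 to 0.056), natural killer (-0.071 to 0.15), prostaglandin (-0.16 to 0.058), oxidative phosphorylation (-0.12 to 0.030), mitochondrial (-0.0057 to 0.15), immediate early (-0.082 to 0.17) and immune tolerance lists (-0.078 to 0.0090), each with fewer libraries. Depth limits the lowest genes: in the pregnant libraries 3 counts are 0.0646 to 0.0680 CPM of the total counts, without TMM scaling.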

Other observations

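The tests of 5 gene lists (chemoattractant receptors, lysosomal proteins, interleukin-1 family, pentose phosphate pathway, DNA damage and mitosis), of scaling by a few abundant genes, of a lower share of lymphocytes and of reads moved between HBA and HBA1 were chosen only after the result was seen. The 5 lists were drawn up on these libraries, so their counts and p-values are not independent evidence of a direction. Chemoattractant receptors, which guide phagocytes to complement fragments, lipids and chemokines, were higher in the pregnant libraries for 10 of 10 genes, with a median log2 fold change of 0.41 (limma camera adjusted p = 5.27e-07 over the 5 lists). The call was lost at adjusted p = 0.0597 with an estimated correlation. Adjusted over the list alone 7 rose, among them the complement receptor C5AR1 (0.39 ± 0.09), the platelet-activating factor receptor PTAFR (0.43 ± 0.10) and CCR1 (0.38 ± 0.10), and 2 of the 10, CXCR1 and CXCR2, are also in the neutrophil list. Lysosomal protein genes were higher for 27 of 29, with a median of 0.13 (camera adjusted p = 2.39e-07; adjusted p = 0.138 with an estimated correlation, the call being lost), and 8 rose when adjusted over the list alone, among them CTSA (0.30 ± 0.07), GM2A (0.42 ± 0.11) and PSAP (0.27 ± 0.09).

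Genes of DNA damage repair and mitosis were lower for 27 of 29, with a median of -0.31 (camera adjusted p = 9.26e-09; adjusted p = 0.0597 with an estimated correlation, the call being lost). Adjusted over the list alone 7 fell, among them the damage kinase ATM (-0.36 ± 0.08), RIF1 (-0.34 ± 0.09) and the centromere protein CENPF (-0.76 ± 0.19). Interleukin-1 family genes had a median of 0.34 over 12 genes (camera adjusted p = 0.00239; adjusted p = 0.133 with an estimated correlation, the call being lost), and 4 of the 12 are also in other lists. Pentose phosphate genes had a median of 0.13 (camera adjusted p = 0.00281; adjusted p = 0.246 with an estimated correlation, the call being lost), with 6 of 7 higher and TKT at 0.36 ± 0.08. For these last lists another split of the libraries gave a smaller p (4.06e-04 and 0.00109, where the real split gave 0.00191 and 0.00281), so neither stood out with pregnancy.

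Granulocyte, inflammatory and MHC class II lists were higher and T cell and cell cycle lists lower, with a gap of 0.54 between the medians of 76 and 49 genes (95% bootstrap interval 0.42 to 0.65). These lists were picked by their direction in these libraries, so a gap was given in advance. The bootstrap resampled genes and not libraries, so its intervals do not measure the spread between libraries. The medians of all 25 tested lists, none picked by direction, had an SD of 0.25. In 95% of draws, random sets of the same sizes and abundance gave 0.0366 to 0.0727. Genes of a list can vary together and genes drawn at random need not, so this comparison cannot decide on scaling by a few abundant genes. Such scaling shifts every gene of a library alike, so it drops out of a gap between lists and cannot make one. Leaving globin, mitochondrial and the most abundant genes out before scaling shifted the median of all genes by 0.000659. That value measures the scaling and does not bear on the gap of 0.54. After correction for a trend with transcript length the gap was 0.51 (interval 0.43 to 0.64), which argues against that trend as the whole source. A candidate explanation for the mature neutrophil list alone is more neutrophils in the samples of pregnant cows. The labels name no sort that would remove these cells. The 8 abundant neutrophil genes, S100A9 (442 ± 12.4 to 529.6 ± 70.6 CPM) and CXCR2 (347 ± 45.0 to 484 ± 54.6 CPM) among them, had a median of 0.35 (interval 0.21 to 0.48) against 0.26 for the list. These 8 genes are part of that list, so their median cannot tell more cells from a higher level within cells. The inflammatory list rested on pregnant library 1 (median 0.09 without it), where the mature neutrophil list was lowest of the pregnant libraries (6.19 log2 CPM), so more neutrophils are not offered as its explanation. Nor are they offered for the eosinophil and basophil or MHC class II lists, higher with medians of 0.49 and 0.22, for which this was not tested. A lower share of all lymphocytes cannot be told apart, since B and natural killer lists lay 0.18 above the T cell list (interval 0.15 to 0.23) but the libraries overlapped in that difference, and pregnancy itself, acting within cells, stays open and untested.

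Red cell genes were higher in the pregnant libraries by a gap to the median of all tested genes of 0.66, the largest of the 25 lists. The furthest of 25 random sets lay 0.0812 to 0.246 away in 95% of draws. Genes drawn at random need not vary together as red cell genes can, so this comparison cannot decide on scaling by a few abundant genes. Such scaling shifts red cell genes and the median of all genes alike, so it drops out of the gap between them and cannot make it. The shift of 0.000659 in the median of all genes, with globin, mitochondrial and abundant genes left out, does not bear on that gap. The summed alpha globins HBA and HBA1 were 3.49-fold higher, above every non-pregnant library in each pregnant one, so reads moved between them are not the whole source. A candidate explanation is more red cell RNA of any kind: the 17 red cell genes other than globins had a median of 0.50 (interval 0.09 to 0.95), 14 of them higher. These 17 genes are part of the list singled out for its largest median, so their median is not independent evidence. HBB was the most abundant red cell gene, at 2316 ± 669 and 4981 ± 2821 CPM. Whether this follows pregnancy or sample handling was not tested.

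Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. For edgeR calls, 10 of 10 splits gave as many (0 in the real split, highest other 1), which says nothing, since any split gives at least 0. For genes at an unadjusted p under 0.05, 1 of 10 did (1530, highest other 1100), as for DESeq2 calls (284, highest other 48), lists past camera (15, highest other 14) and cell type lists with groups apart (6, highest other 3).

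Genes were also grouped by the stem of their symbol, a grouping chosen after the data were seen. Of 156 stems, 4 passed camera at the preset correlation (MRPL, RPL, CEP and RPS) and 0 with an estimated correlation.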
